A study of Mus musculus with 22 samples.

How the data were processed

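RNA of mouse aortic endothelial cells was hybridised to 22 Affymetrix 3-prime expression arrays, 1 per sample. Per the labels' protocols, aortas were opened, the intima was scraped off, and the RNA, with an integrity number of at least 7.0, was amplified and biotin labelled. Samples were either taken fresh or kept for 4 h in medium with 1% serum, alone or with 1 of 3 stimuli. The deposited values are log2 signals made with RMA in the affy package, per the submitters' processing notes, which give no versions. RMA subtracts background, quantile normalizes and summarises the probes of each probe set. Whether all arrays were normalized together is not stated, but their medians and quartiles were nearly equal. Quantile normalization sets these equal by construction, so a shift of most transcripts in 1 direction would not be visible. Raw intensities, detection calls and control probe sets were not used here.

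Probe sets were named through the platform's annotation and updated by gene identifier from a mouse RefSeq table of assembly GRCm38.p6, used only for names and for which genes neighbour each other. The sources used here give no genome build. Of 22626 probe sets, 18003 carried 1 symbol, 287 several and 4336 none, and 17977 matched the RefSeq table. Probe sets with several symbols or none were left out. The remaining probe sets named 11807 genes, of which 4150 had more than 1 probe set. Each gene was represented by its probe set with the highest mean over all 22 arrays. Among the other probe sets of called genes, 13 of 13 moved in the same direction in the ApoE comparison, 287 of 377 with LPS, 98 of 129 with oxLDL, 792 of 965 with oxPAPC and 2355 of 2454 after incubation in medium. Among the direct comparisons of stimuli the numbers were 161 of 242 for LPS against oxLDL, 362 of 381 for LPS against oxPAPC and 477 of 601 for oxLDL against oxPAPC. A second probe set was called in the opposite direction for 3 with LPS, 10 with oxPAPC, 23 after incubation, 2 for LPS against oxLDL and 6 for oxLDL against oxPAPC.

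Genes entered a fit if they lay above the 40th percentile of their array in at least as many arrays as the smallest group compared. This left 7264 genes for the fresh arrays, 7550 for the 12 incubated arrays and 7508 for medium against fresh wild type. Differences were tested with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Where 1 of the groups compared averaged below the 40th percentile of its arrays, the size of a change depends on values near background, so such genes are named beside each comparison with, for the leading ones, the distance of the other group from that percentile. The fresh comparison used the 10 fresh arrays alone. The 4 incubated groups were fitted together and shared 1 estimate of the spread. Every ± in the text is a standard error from these fits unless SD is written, and adjusted p-values come from limma or, for gene lists, from camera in limma. The labels do not say how many animals went into an array, so the p-values measure only the spread between arrays.

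Gene lists for pathways, stress responses and cell types were fixed before the data were examined, as were the groups, the tests and the alternatives. They held 616 entries in 32 lists, of which 530 entries were on the array, 5 of them through an older symbol. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. In the fresh comparison 5 lists had too few tested genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. The genes named in the text were fixed by rule: the 8 largest rises and the 8 largest falls among called genes, up to 3 called members of each list, Apoe itself, and in a list with no call its member with the smallest p. A gene named for 1 comparison could be named in another. Apoe lay below the level filter and was tested on its own by an exact permutation test.

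For the ex vivo responses, the 100 genes with the highest and the 100 with the lowest moderated t of each stimulus were tested by camera in the fresh comparison. The overlap of calls between stimuli was set against 100 simulated draws of unchanged groups that shared 3 simulated control arrays, and against the overlap of independent lists. Called genes within 10 Mb of Apoe were compared with all others by Fisher's exact test.

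The fits were tested on simulated data with known changes. In the design of the fresh comparison, with 7264 genes, 49.3%, 94% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 7 false calls among 169. For LPS against medium, with 7550 genes, recovery was 10.4%, 70.1% and 100%, with 4 false calls among 124. For medium against fresh wild type, with 7508 genes, it was 20.9%, 83.6% and 98.5%, with 4 false calls among 139. The simulated noise was independent between genes and between arrays. Structure that many genes share on the real arrays was left out, so these rates need not hold there.

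Alternatives were no level filter, a filter at the 60th percentile, every probe set on its own, the mean of a gene's probe sets, cyclic loess and median centring of the deposited values, eBayes with a trend and robust priors, array weights, all 22 arrays in 1 fit, only the arrays of the 2 groups compared, an added 2-fold threshold, each array left out in turn, and the mean of the smooth muscle markers per array as a covariate.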

Results

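Transcript levels were measured on 22 arrays of mouse aortic endothelial cells in 6 groups. Fresh intima came from 4-week-old ApoE-knockout mice (n = 4), labelled as hyperlipidemic before lesions form, and from wild-type mice (n = 6). Both were of the same age and on chow, and their sample titles carry the strain label BL6. Samples of 4 further groups were incubated for 4 h in medium, alone or with 1 of 3 stimuli (n = 3 each). These were bacterial lipopolysaccharide (LPS, 4 ng/mL), oxidized low-density lipoprotein (oxLDL, 50 µg/mL) and oxidized palmitoyl-arachidonoyl-phosphocholine (oxPAPC, 50 µg/mL), a mixture of oxidized phospholipids. The small number of arrays per group limits the precision of every value. Arrays of 1 group correlated at r = 0.9774 to 0.9906 across genes, and fresh with incubated arrays at 0.9115 to 0.9377. The first principal component, which separated fresh from incubated arrays, held 59.2% of the variance. Within groups, the arrays that stood farthest apart were in the oxPAPC group (lowest r = 0.9774).

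The fresh arrays compare intima of ApoE-knockout and wild-type mice before lesions form, so hyperlipidemia and the loss of Apoe itself go together. Apoe itself measured 3.04, 3.04, 3.23 and 3.14 on the log2 scale in knockout replicates 3, 4, 5 and 6. It measured 4.09, 4.35, 3.78, 4.19, 3.99 and 4.23 in wild-type replicates 7, 8, 12, 13, 14 and 15. The difference was −0.997 (SD 0.0906, n = 4 and 0.198, n = 6; exact permutation p = 0.00476, the smallest that 210 splits allow). All values lay below the 40th percentile of their array, and whether the probe set lies in the deleted part of the gene is not known here. The 12 incubated arrays gave 3.06 to 3.89, and the oxPAPC group (3.14, SD 0.0662, n = 3) lay within the knockout range.

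Knockout intima carried more transcript for an adhesion receptor and a cholesterol exporter. It carried less for a platelet chemokine, a protease inhibitor and an anticoagulant. Only the call of the adhesion receptor, Nectin2, held with every array left out and with the smooth muscle markers as a covariate. For the others that covariate gave adjusted p-values of 0.433 to 0.514 in limma. Nectin2, a cell adhesion receptor of the immunoglobulin family, was 4.04-fold higher (log2 2.01 ± 0.10, adjusted p = 1.22e-06, n = 4 and 6), and its second probe set also differed by 0.56 ± 0.0946. Abcg1, which exports cholesterol to lipoproteins and is induced by oxysterols, rose 2.49-fold (1.32 ± 0.21, adjusted p = 0.0393). Ppbp, a platelet chemokine, fell by 2.93 ± 0.53 (adjusted p = 0.0427), and Serpina1b, a secreted protease inhibitor, fell by 2.59 ± 0.43 (adjusted p = 0.0417). Thbd, the endothelial anticoagulant thrombomodulin, fell by 0.58 ± 0.10 (adjusted p = 0.0417).

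Besides Nectin2 and Abcg1, the genes that rose included Tnnt2, a cardiac troponin (1.39 ± 0.26), Phkg1 (1.02 ± 0.15), Cuedc1 (0.98 ± 0.17), the collagen receptor Ddr2 (0.96 ± 0.16), Cpne2 (0.79 ± 0.13) and the laminin chain Lamc1 (0.74 ± 0.10). Further falls were measured for H2-M3, a nonclassical class I molecule (−1.19 ± 0.18), the phosphatase receptor Ptprg (−0.96 ± 0.18), Camk1d (−0.94 ± 0.18), the cyclin Ccnd1 (−0.94 ± 0.16), the adhesion molecule L1cam (−0.92 ± 0.17), Gna14 (−0.90 ± 0.16), Skil (−0.61 ± 0.10) and Idi1, an enzyme of isoprenoid synthesis (−0.67 ± 0.11). In total 31 of 7264 genes passed the test, 10 higher and 21 lower. Median centring gave 7 higher and 8 lower. Ppbp and Serpina1b in the knockout and Tnnt2 in wild type averaged below the 40th percentile of their arrays, and the other group lay 1.78, 1.58 and 1.08 above that level.

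Of 9 tested LXR targets, the genes that oxysterol receptors induce, 1 rose (Abcg1) and none fell, while 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0716). Among 11 antigen-presentation genes none passed over all genes and 3 fell adjusted over the list alone. H2-Ab1, a class II chain, measured −1.78 ± 0.41 (adjusted p = 0.0828). As a group they lay lower (camera adjusted p = 0.000212, adjusted p = 0.555 with an estimated correlation). The 21 interferon-response genes lay lower by a median of 0.396 in the same test (camera adjusted p = 0.00702, adjusted p = 0.867 with an estimated correlation), with none called over all genes or adjusted over the list alone. In the erythroid and platelet list 1 of 8 fell (Ppbp), 3 adjusted over the list alone (camera adjusted p = 0.00508, adjusted p = 0.555 with an estimated correlation). Of 29 oxidative phosphorylation genes 1 fell, both over all genes and adjusted over the list alone: Cox5a, a subunit of cytochrome oxidase (−0.60 ± 0.11). This list passed camera (adjusted p = 0.0193, adjusted p = 0.555 with an estimated correlation) but not after cyclic loess scaling, where the median went from −0.11 to −0.06 (adjusted p = 0.113).

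Smooth muscle markers moved with these groups. Of 16, none passed over all genes, 9 were higher adjusted over the list alone, and their median was 0.49 higher in the knockout (camera adjusted p = 3.09e-07, adjusted p = 0.555 with an estimated correlation). Des measured 0.80 ± 0.22 (adjusted p = 0.107). None of 17 endothelial markers passed over all genes (median −0.06, camera adjusted p = 0.871). With the smooth muscle markers as a covariate, which made the standard errors 1.46 times as large, the interferon median went from −0.40 to −0.31 (adjusted p = 0.0677) and that of erythroid and platelet genes from −0.38 to −0.16 (adjusted p = 0.126), and both lost their calls. Antigen presentation (−0.50 to −0.33, adjusted p = 0.0225) and oxidative phosphorylation (−0.11 to −0.15, adjusted p = 0.0073) kept them. LXR targets (adjusted p = 0.017, median 0.47) and endothelial markers (adjusted p = 0.0107, median 0.17) then passed as higher, and immediate early (adjusted p = 0.00404) and heat shock genes (adjusted p = 0.0224) as lower. Vcam1 measured −0.60 ± 0.17 (adjusted p = 0.127).

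The count of called genes rested on single arrays. It was 1 without knockout replicate 3 or 5 and without wild-type replicate 7 or 13, 2 without knockout replicate 6, and 4 without knockout replicate 4 or wild-type replicate 8. It was 47 without wild-type replicate 15 and 68 without wild-type replicate 12, in which endothelial markers were lowest (8.25) and smooth muscle markers stood at 9.24. Nectin2 alone among the 20 named genes passed under every array left out (1.96 to 2.06) and with the smooth muscle markers as a covariate, which called 1 gene in all. Of the 20, 11 passed with both other scalings, and the Ppbp call was lost with median centring at nearly the same change (−2.89, adjusted p = 0.0524). Of 101 tested genes within 10 Mb of Apoe 1 was called (Nectin2), against 30 of 7153 elsewhere (Fisher's exact p = 0.353).

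**Figure D1:**
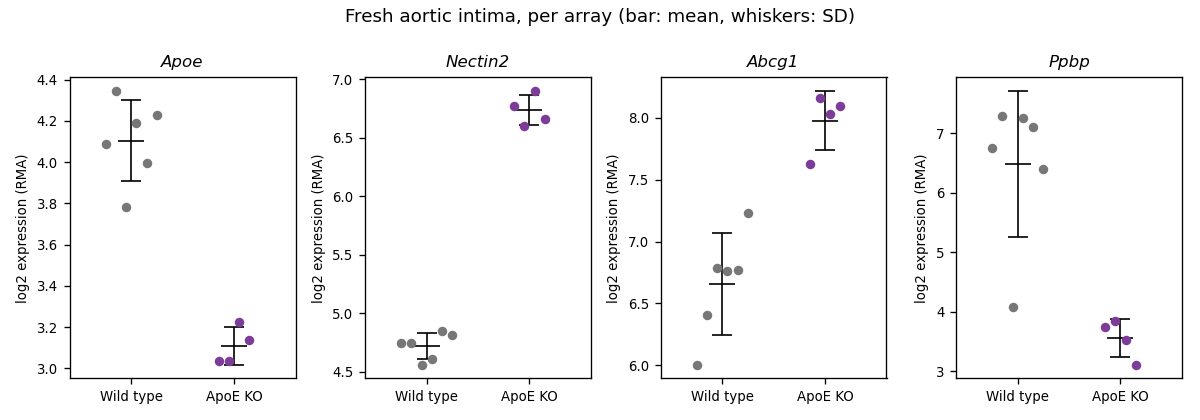
Log2 expression of Apoe, Nectin2, Abcg1 and Ppbp on each fresh array (points), with group means (bars) and SD (whiskers), knockout n = 4 and wild type n = 6. Nectin2 averaged 6.74 in the knockout and 4.72 in wild type without overlap, and Ppbp in wild-type replicate 12 (4.08) lay near the knockout arrays.

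LPS, here at 4 ng/mL, is a bacterial activator of endothelial cells, and its arrays were compared with medium alone for 4 h. The lists of interferon-response genes and of cytokines and chemokines lay highest (median 1.13 each), calls lost with an estimated correlation (adjusted p = 0.344 and 0.134). Cxcl10, a chemokine for T cells, rose 30.5-fold (log2 4.93 ± 0.34, adjusted p = 1.93e-05, n = 3 and 3). The antiviral gene Rsad2 rose by 3.73 ± 0.38 (adjusted p = 0.00041) and the collagenase Mmp13 by 3.57 ± 0.34 (adjusted p = 0.000392). The largest falls were Sprr1a (−3.71 ± 0.93, adjusted p = 0.0324), Hpgd, which degrades prostaglandins (−2.95), and the iron exporter Slc40a1 (−2.27 ± 0.31, adjusted p = 0.00211).

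Of 24 interferon-response genes 11 rose and none fell, 17 rose adjusted over the list alone (camera adjusted p = 1.12e-12, adjusted p = 0.344 with an estimated correlation). Beside Cxcl10 and Rsad2 they included Ifit1 (3.17 ± 0.41) and Ifit3 (3.06 ± 0.41), and the interferon-inducible Ifi209, outside the list, rose by 3.54 ± 0.24. Of 13 inflammatory cytokines and chemokines 7 rose, 10 adjusted over the list alone (camera adjusted p = 2.66e-08, adjusted p = 0.134 with an estimated correlation), among them Ccl5 (2.83 ± 0.23, adjusted p = 8.41e-05), Il1b (1.65 ± 0.28, adjusted p = 0.00651) and the growth factor Csf2 (1.62). Feedback genes of NF-kB signalling followed, with 8 of 15 higher, 9 adjusted over the list alone (camera adjusted p = 1.07e-06, adjusted p = 0.161 with an estimated correlation). Tnfaip3, which ends NF-kB signalling, rose by 1.37 ± 0.22, the mitochondrial superoxide dismutase Sod2 by 1.27 ± 0.22 and Nfkbie by 1.25. The cystine transporter Slc7a11 (1.68), the Fc receptor Fcgr1 (1.12), the protease Plau (0.98) and the proliferation marker Mki67 (0.83) rose too. Among 12 leukocyte adhesion genes none rose and 1 fell, Icam2, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.459). Sele measured 0.85 ± 0.30 (adjusted p = 0.0891) and Vcam1 0.71 ± 0.25 (adjusted p = 0.0909). In medium alone Sele was already 2.98 higher than in fresh wild type.

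Endothelial markers moved the other way: 5 of 17 fell, 7 adjusted over the list alone (median −0.51, camera adjusted p = 0.0114, adjusted p = 0.685 with an estimated correlation). Clec14a, an endothelial lectin, fell by 1.29 ± 0.26, Egfl7 by 1.06 ± 0.19, Icam2 by 0.83 and Vwf, von Willebrand factor, by 0.66. Of 19 genes of endothelial quiescence and nitric oxide signalling 1 fell, also adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.147 with an estimated correlation). Notch1, a receptor of arterial endothelium, fell by 0.96 ± 0.13 (adjusted p = 0.002). Lists of lipid handling did not pass: 3 of 18 PPAR targets were lower (camera adjusted p = 0.126) and 3 of 9 LXR targets (camera adjusted p = 0.17), also adjusted over the list alone. Single falls among them were Fabp5, a fatty acid carrier (−1.94 ± 0.24, adjusted p = 0.00132), the fatty acid transporter Cd36 (−1.44), the lipase Lpl (−1.41), Mylip, which degrades the LDL receptor (−1.33), and Abcg1 (−1.04). Of 15 macrophage markers 4 fell and 1 rose, 9 and 1 adjusted over the list alone (camera adjusted p = 0.0184, adjusted p = 0.685 with an estimated correlation), with C1qc at −1.42, Tyrobp at −1.12 and Cd68 at −1.09. Other falls were Rmnd5b (−2.12 ± 0.24, adjusted p = 0.00089), complement C4b (−2.11), Slc15a2 (−2.03), Igfbp3 (−2.02) and Cdca7l (−1.95). Smooth muscle markers were higher, 3 of 16 over all genes and 10 adjusted over the list alone (median 0.72, camera adjusted p = 1.07e-06, adjusted p = 0.505 with an estimated correlation), with Lmod1 at 0.90 ± 0.24, Myh11 at 0.86 and Tpm2 at 0.81. With these markers as a covariate the interferon, cytokine and NF-kB lists kept their calls (adjusted p = 1.31e-16, 7.28e-09 and 1.09e-07) at medians of 1.39, 1.44 and 0.92. Standard errors were then 1.43 times as large. The calls of endothelial markers (median −0.51 to −0.22, adjusted p = 0.359), quiescence genes (−0.40 to −0.37, adjusted p = 0.174) and macrophage markers (−0.60 to −0.49, adjusted p = 0.249) were lost, the quiescence median with little change, and hypoxia (adjusted p = 0.0101) and TGF-beta matrix genes (adjusted p = 0.0407) passed as lower.

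Ccl5, Csf2, Fcgr1, Ifi209, Mmp13, Nfkbie and Tnfaip3 averaged below the 40th percentile of their arrays in medium, as did Hpgd, Slc15a2 and Slc40a1 with LPS. Mmp13 with LPS and Hpgd in medium lay 3.04 and 2.03 above that level. Of 7550 genes 683 changed with LPS, 254 higher and 429 lower. Cyclic loess gave 321 higher and 344 lower, and median centring 435 and 273, with the median of all genes moving from −0.03 to 0.07. The count was 236, 351 and 312 without medium replicates 9, 10 and 11, and 314, 274 and 374 without LPS replicates 3, 4 and 10. It was 118 with the smooth muscle markers as a covariate. Of 59 named genes 23 passed under every array left out, Cxcl10, Rsad2, Ifit1, Ccl5, Il1b, Tnfaip3, Slc40a1 and Egfl7 among them.

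The lipoprotein arm asked what oxLDL, at 50 µg/mL, changes within 4 h. No cytokine, NF-kB feedback, interferon-response or leukocyte adhesion gene was called, with 1635 of all genes at an unadjusted p under 0.05 in limma. Against fresh wild type, medium alone had already raised 8 cytokines (1 fell) and 10 NF-kB feedback genes, while 8 interferon-response genes fell. In simulated data for LPS against medium, also 3 against 3 arrays, 10.4% of changes of 0.5 were recovered. The lack of calls therefore cannot show that oxLDL has no inflammatory effect. Lamb1, a laminin chain, fell by 2.12 ± 0.38 (adjusted p = 0.0179, n = 3 and 3), the basement membrane proteoglycan Hspg2 by 1.71 ± 0.28 (adjusted p = 0.0149) and the small proteoglycan Lum by 1.56 ± 0.30 (adjusted p = 0.0207). Emcn, an endothelial sialomucin, fell by 1.13 ± 0.16 (adjusted p = 0.00793), and Fabp5 by 1.36 ± 0.24 (adjusted p = 0.0179). Stambpl1, a deubiquitinase, had the largest rise (1.49 ± 0.22, adjusted p = 0.00793).

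Further rises were Pcp2 (1.40), the glycosyltransferase B3galnt2 (1.29), Ccn5 (1.27), lactate dehydrogenase Ldhb (1.27), Tbx15 (1.24), the lysosomal protein Tmem106b (1.18), Zkscan14 (1.16), the early gene Nr4a2 (0.73) and the apoptosis gene Bbc3 (0.64). Further falls were Rab26os (−2.07), Tbc1d14 (−1.93), the actin regulator Eps8 (−1.91), Gid8 (−1.87 ± 0.22), Ythdf3, a reader of methylated RNA (−1.63 ± 0.16, adjusted p = 0.00168), the peptidase Anpep (−1.63), the proteoglycan Dcn (−0.76), Ace, the angiotensin-converting enzyme (−0.68), and the respiratory subunit Uqcrc2 (−0.62).

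None of 24 interferon-response genes, 13 cytokines or 11 sterol synthesis genes passed the limma test over all genes, and 2 interferon-response genes were lower adjusted over the list alone. Nor did any of the 19 genes of the TGF-beta matrix list (camera adjusted p = 0.844). Of 11 fibroblast markers 2 fell, Lum and Dcn, with 2 higher and 2 lower adjusted over the list alone (median 0.23, camera adjusted p = 0.799). Ifit1 measured −1.66 ± 0.41 (adjusted p = 0.0531). None of 23 NRF2 targets, which respond to oxidants and electrophiles, was called over all genes and 2 were higher adjusted over the list alone (camera adjusted p = 0.0956). Their member Txnrd1 measured 0.46 ± 0.13 (adjusted p = 0.0689). Of 17 endothelial markers 1 fell (camera adjusted p = 0.116). Among 15 macrophage markers 1 fell, C1qa (−0.88), and 3 adjusted over the list alone (median −0.48, camera adjusted p = 0.0366, adjusted p = 0.996 with an estimated correlation). Of 7 erythroid and platelet genes 1 fell, the globin Hba-a2 (−0.84), also adjusted over the list alone (camera adjusted p = 0.0366, adjusted p = 0.996 with an estimated correlation). No smooth muscle marker of 16 passed over all genes, 6 were higher adjusted over the list alone, and the median was 0.63 (camera adjusted p = 1.6e-05, adjusted p = 0.996 with an estimated correlation). Myocd, a smooth muscle transcription cofactor, measured 0.90 ± 0.24 (adjusted p = 0.0668). With these markers as a covariate, which made the standard errors 1.35 times as large, the macrophage call was lost without a smaller median (−0.48 to −0.52, adjusted p = 0.46), and the erythroid and platelet call with one (−0.77 to −0.40, adjusted p = 0.488). NRF2 targets then passed as higher (adjusted p = 0.00641, median 0.31) and hypoxia genes as lower (adjusted p = 0.00641, median −0.50).

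Pcp2 and Tbx15 in medium and Lum with oxLDL averaged below the 40th percentile of their arrays. In all 212 of 7550 genes changed with oxLDL, 56 higher and 156 lower, and median centring gave 148 higher and 132 lower. The count was 23, 92 and 119 without medium replicates 9, 10 and 11, 36 and 60 without oxLDL replicates 15 and 16, and 16 with the smooth muscle covariate. It was 64 with only the 2 groups in the fit. Of 27 named genes only Emcn, Gid8 and Ythdf3 passed under every array left out.

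The phospholipid arm asked the same of oxPAPC, also at 50 µg/mL. Lists of NRF2 targets, which act against oxidants (14 of 23 higher), sterol synthesis (5 of 11) and heat shock genes (8 of 12) lay higher and endothelial markers lower (10 of 17), calls all lost with an estimated correlation (adjusted p = 0.354 to 0.355). Gclm, which limits glutathione synthesis, rose by 2.39 ± 0.25 (adjusted p = 0.000504, n = 3 and 3). Sqle, squalene epoxidase, rose by 1.86 ± 0.31 (adjusted p = 0.00322). Il1b fell by 2.15 ± 0.28 (adjusted p = 0.00104) and the chemokine Cxcl12 fell by 2.55 ± 0.22 (adjusted p = 0.000196). The largest fall was Igfbp3, a binding protein of insulin-like growth factors (−3.89 ± 0.52, adjusted p = 0.00109), whose level in medium lay 2.93 above the 40th percentile of the oxPAPC arrays. Ccl2, Igfbp3 and Il6 with oxPAPC and Kcnj15 and Rasl2-9 in medium averaged below that percentile of their arrays.

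Of 23 NRF2 targets 14 rose and none fell, 16 adjusted over the list alone (camera adjusted p = 6.27e-10, adjusted p = 0.354 with an estimated correlation). Beside Gclm, the cystine transporter Slc7a11 rose by 2.08 ± 0.43, the quinone reductase Nqo1 by 1.75, Srxn1 by 1.72 and heme oxygenase Hmox1 by 1.52. Sterol synthesis genes were higher for 5 of 11, 6 adjusted over the list alone (camera adjusted p = 7.3e-05, adjusted p = 0.354 with an estimated correlation), with Idi1 at 1.59 ± 0.31 and Hsd17b7 at 1.33 ± 0.21. Of 12 heat shock genes 8 rose, also adjusted over the list alone (camera adjusted p = 4.07e-05, adjusted p = 0.354 with an estimated correlation), with Hspa1b at 1.09 ± 0.30, Cryab at 1.06 and Dnajb4 at 0.88. Immediate early genes split into 5 higher and 2 lower of 18, also adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.407 with an estimated correlation). The nuclear receptors Nr4a2 (1.71 ± 0.17, adjusted p = 0.000504) and Nr4a1 (1.58 ± 0.19) led them. Outside the lists, the transketolase-like Tktl1 (2.78 ± 0.38), Ptprz1 (2.39), Rasl2-9 (2.38), the nitric oxide receptor subunit Gucy1b1 (2.04), Kcnj15 (2.01) and the retinol carrier Rbp4 (1.98) rose most.

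Endothelial markers were lower for 10 of 17, also adjusted over the list alone (median −0.86, range −1.56 to 0.38, camera adjusted p = 3.31e-05, adjusted p = 0.355 with an estimated correlation). The junction protein Cldn5 fell by 1.56 ± 0.30, Egfl7 by 1.51 ± 0.19, the TGF-beta coreceptor Eng by 1.32 ± 0.17, Icam2 by 1.28 and Vwf by 1.11 ± 0.17. In the list of endothelial quiescence and nitric oxide signalling 7 of 19 fell and 1 rose, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0459, adjusted p = 0.354 with an estimated correlation), and Nos3, the endothelial nitric oxide synthase, fell by 1.43. Of 12 coagulation and fibrinolysis genes 5 fell, 6 adjusted over the list alone (camera adjusted p = 0.00905, adjusted p = 0.355 with an estimated correlation), such as the plasminogen activator Plat (−1.85). Scavenger receptors fell for 4 of 10, also adjusted over the list alone (camera adjusted p = 0.0429, adjusted p = 0.354 with an estimated correlation), with Olr1, the endothelial receptor for oxLDL, at −2.65 ± 0.57 (adjusted p = 0.00909) and Stab1 at −1.24. Olr1 measured 8.256 in oxPAPC replicate 13, against 5.539 and 5.699 in replicates 11 and 12, and its change was −3.53 without that array. Endothelial markers were highest there as well (8.345, against 7.883 and 7.969). The arterial connexins Gja4 and Gja5 fell by 1.54 and 1.17, and the leukocyte receptor Selp by 1.46.

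Among inflammatory genes, 4 of 15 NF-kB feedback genes fell, also adjusted over the list alone (camera adjusted p = 0.0206, adjusted p = 0.407 with an estimated correlation), with Bcl3 at −1.84 ± 0.28, Tnfaip2 at −1.42 and Tnip1 at −1.32. Cytokines split into 2 higher and 4 lower of 13, 2 and 5 adjusted over the list alone (camera adjusted p = 0.371), the lower ones with Il6 (−2.26 ± 0.67, adjusted p = 0.0337), Il1b and Ccl2 (−1.33). Of 11 antigen-presentation genes 4 fell, 6 adjusted over the list alone (camera adjusted p = 0.00392, adjusted p = 0.407 with an estimated correlation), with H2-Eb1 at −1.24 and Cd74 at −0.99. Of 15 macrophage markers 8 fell, 9 adjusted over the list alone (median −0.76, camera adjusted p = 0.000476, adjusted p = 0.388 with an estimated correlation), with C1qc at −1.18 and Cd68 at −0.96. The ATF4 list of amino acid stress had 7 lower and 1 higher of 20, also adjusted over the list alone (camera adjusted p = 0.0258, adjusted p = 0.407 with an estimated correlation). Its members Trib3 and Ddit3 fell by 1.10 and 1.01. Ribosomal genes fell for 4 of 21, 7 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.55 with an estimated correlation). Oxidative phosphorylation fell for 4 of 29, none adjusted over the list alone (camera adjusted p = 0.0359, adjusted p = 0.589 with an estimated correlation), a call lost with cyclic loess (median −0.21 to −0.14, adjusted p = 0.0771) and median centring (−0.08, adjusted p = 0.0561). Interferon-response genes, of which 3 of 24 fell, missed camera's threshold (adjusted p = 0.053) and passed it, lower, with either scaling (adjusted p = 0.0484 and 0.0217).

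Smooth muscle markers rose alongside, 12 of 16 over all genes and 14 adjusted over the list alone (median 1.02, camera adjusted p = 4.26e-08, adjusted p = 0.354 with an estimated correlation). Kcnmb1, a potassium channel subunit of smooth muscle, rose by 1.93 ± 0.37, the myosin light chain Myl9 by 1.25 and Myocd by 1.19. Postn (1.64) and Ogn (1.75), both matrix genes, rose as well. In all 1606 of 7550 genes changed with oxPAPC, 630 higher and 976 lower. Median centring gave 1044 higher and 646 lower, and moved the median of all genes from −0.05 to 0.09. With the smooth muscle markers as a covariate limma called no gene (smallest adjusted p = 0.058, 1089 genes at an unadjusted p under 0.05). The standard errors were then 1.74 times as large, 1581 of the 1606 genes kept their sign, and Gclm measured 2.45 ± 0.45. NRF2 (median 0.84 to 0.87), sterol (0.87 to 0.75) and heat shock lists (0.55 to 0.57) stayed higher under that covariate (camera adjusted p = 1.69e-14, 0.00177 and 0.00071). Endothelial markers stayed lower at a smaller median (−0.86 to −0.46, adjusted p = 0.00724), and hypoxia genes passed as lower (0.00327). Other calls were lost with medians about as large or larger: macrophage (−0.76 to −0.62, adjusted p = 0.0808), scavenger receptor (−0.31 to −0.51, 0.0983), immediate early (0.22 to 0.29, 0.0808) and oxidative phosphorylation genes (−0.21 to −0.26, 0.113). Medians shrank for the lost calls of NF-kB feedback (−0.32 to −0.12, adjusted p = 0.451), antigen presentation (−0.48 to −0.21, 0.427), coagulation (−0.53 to −0.30, 0.218), quiescence (−0.29 to −0.17, 0.218), ATF4 (−0.35 to −0.21, 0.118) and ribosomal genes (−0.23 to −0.05, 0.766). Col3a1 turned from a rise to −0.17 and Rbp4 to −0.06. Myl9 turned to −0.05, but it is 1 of the markers averaged into the covariate, so its loss is partly built in. The count was 783, 1058 and 1018 without medium replicates 9, 10 and 11, and 768 and 735 without oxPAPC replicates 11 and 12.

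**Figure D2:**
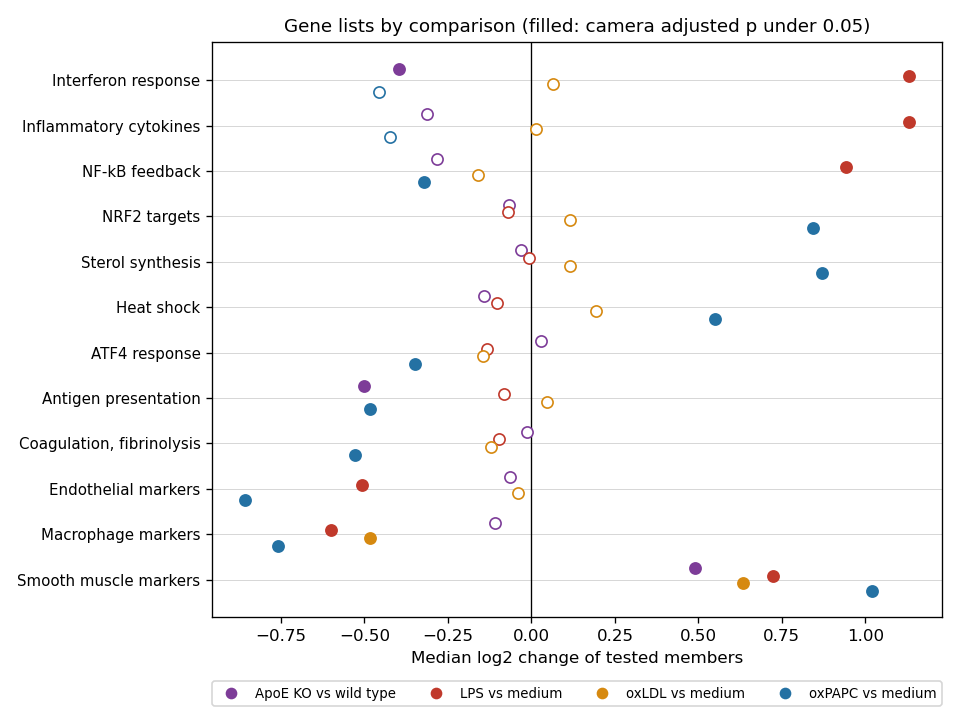
Median log2 change of the tested members of 12 gene lists (y axis) in the knockout and with each stimulus (colours), filled where camera's adjusted p was under 0.05. The interferon, cytokine and NF-kB lists lie highest for LPS, the NRF2, sterol and heat shock lists for oxPAPC, and smooth muscle markers are higher in all 4 comparisons.

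OxLDL and oxPAPC, given at the same dose, were compared directly, and 934 of 7550 genes differed, 589 higher with oxLDL and 345 higher with oxPAPC. Cyclic loess gave 473 and 434. The lists of NRF2 targets and sterol synthesis lay higher with oxPAPC, and those of endothelial markers and antigen presentation with oxLDL (7 of 17 and 2 of 11 called), calls lost with an estimated correlation (adjusted p = 0.493 to 0.61). No inflammatory list passed: cytokines had 2 higher and 1 lower of 13 (camera adjusted p = 0.512), NF-kB feedback 3 higher of 15, with 1 lower adjusted over the list alone (0.252), leukocyte adhesion 1 of 12, 4 adjusted over the list alone (0.181), and interferon 2 of 24 (0.0933). NRF2 targets were lower with oxLDL for 10 of 23, 13 adjusted over the list alone (camera adjusted p = 3.6e-08, adjusted p = 0.493 with an estimated correlation): Gclm differed by −2.27 ± 0.25 (adjusted p = 0.000881, n = 3 and 3), Slc7a11 by −2.20 and Hmox1 by −1.43 ± 0.23. Catalase, Cat, outside the list, differed by −2.26. Sterol synthesis genes were lower for 7 of 11, 8 adjusted over the list alone (camera adjusted p = 6.6e-06, adjusted p = 0.493 with an estimated correlation), with Sqle at −2.02 ± 0.31 (adjusted p = 0.00323) and the regulator Srebf2, below the 40th percentile of its arrays with oxLDL, at −1.19. Of 12 heat shock genes 2 were lower, also adjusted over the list alone (camera adjusted p = 0.00151, adjusted p = 0.583 with an estimated correlation), and of 18 immediate early genes 4 were lower and 2 higher, 5 and 2 adjusted over the list alone (camera adjusted p = 0.0074, adjusted p = 0.583 with an estimated correlation), with Nr4a1 at −1.25.

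Higher with oxLDL were 7 of 17 endothelial markers, 8 adjusted over the list alone (camera adjusted p = 0.00192, adjusted p = 0.61 with an estimated correlation), with Cldn5 at 1.97 ± 0.30, the receptor Tie1 at 1.26 and Vwf at 1.15. Antigen-presentation genes were higher for 2 of 11, 6 adjusted over the list alone (camera adjusted p = 0.00151, adjusted p = 0.583 with an estimated correlation), and coagulation genes for 3 of 12, 4 adjusted over the list alone (camera adjusted p = 0.0228, adjusted p = 0.583 with an estimated correlation). Single genes higher with oxLDL were Olr1 (2.47 ± 0.57), Il1b (2.22 ± 0.28), Cxcl12 (2.09 ± 0.22, adjusted p = 0.000647), Bcl3 (1.53) and Abcg1 (1.39). The lipase Lpl (−1.65), the iron exporter Slc40a1 (−2.16), the oxidase Nox4 (−2.14) and Tktl1 (−2.28) were lower. Smooth muscle markers were lower for 1 of 16, also adjusted over the list alone (median −0.35, camera adjusted p = 0.0111, adjusted p = 0.685 with an estimated correlation). Lamb1, which fell with both, differed by 0.60 ± 0.38 (adjusted p = 0.327), so a difference of either sign cannot be excluded. With the smooth muscle covariate, under which standard errors were 1.14 times as large, the coagulation call was lost with little change in its median (0.40 to 0.38, adjusted p = 0.0867), while endothelial markers (0.69 to 0.49) and antigen presentation (0.52 to 0.40) kept theirs at smaller medians (adjusted p = 0.0124 each). The count was 434 without oxLDL replicate 16, 388 and 348 without oxPAPC replicates 11 and 12, and 379 with the smooth muscle covariate. With only the 2 groups in the fit it was 543.

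LPS was set against oxLDL and oxPAPC at a different dose (4 ng/mL against 50 µg/mL), so differences cover agent and dose together. Against oxLDL, 383 genes differed, 167 higher with LPS and 216 lower, and cyclic loess gave 219 and 166. Cxcl10 (5.11 ± 0.34, adjusted p = 2.54e-05), Ifit1 (4.82 ± 0.41), Mmp13 (3.99), Ccl5 (3.23), the interleukin-1 antagonist Il1rn (2.82), Il6 (2.58) and Cxcl5 (2.14) were higher, and Vcam1 too (1.07 ± 0.25, adjusted p = 0.032). Interferon-response genes were higher for 10 of 24, 17 adjusted over the list alone (camera adjusted p = 1.69e-16, adjusted p = 0.234 with an estimated correlation), cytokines for 8 of 13, 9 adjusted over the list alone (camera adjusted p = 1.78e-11, adjusted p = 0.0534 with an estimated correlation), and NF-kB feedback genes for 7 of 15, 9 adjusted over the list alone (camera adjusted p = 1.78e-11, adjusted p = 0.0542 with an estimated correlation). Hpgd (−2.52), Tnfsf13 (−1.58), Slc40a1 (−1.54) and Osgin1 (−1.48) were lower. Ccl5, Cxcl10, Cxcl5, Il6 and Mmp13 with oxLDL and Hpgd and Slc40a1 with LPS averaged below the 40th percentile of their arrays. The count was 177, 133 and 234 without LPS replicates 3, 4 and 10, and 156 and 143 without oxLDL replicates 15 and 16. With only the 2 groups it was 210.

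Against oxPAPC, 653 genes differed, 354 higher with LPS and 299 lower. Interferon-response genes were higher for 18 of 24, 21 adjusted over the list alone (camera adjusted p = 5.72e-19, adjusted p = 0.153 with an estimated correlation). NF-kB feedback genes were higher for 10 of 15, 14 adjusted over the list alone, and cytokines for 8 of 13, 10 adjusted over the list alone. Both passed camera (adjusted p = 1.13e-12 and 3.8e-10) and kept their calls with an estimated correlation (adjusted p = 0.0409 each). Il1b differed by 3.81 ± 0.28 (adjusted p = 2.45e-05, n = 3 and 3), Il6 by 3.39, Tnip1 by 2.47, Birc3 by 2.21, Sele by 1.71 ± 0.30 and Vcam1 by 1.66. Leukocyte adhesion genes were higher for 4 of 12, also adjusted over the list alone (camera adjusted p = 0.00756, adjusted p = 0.337 with an estimated correlation). Endothelial markers were higher for 5 of 17 and lower for 1, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00259, adjusted p = 0.454 with an estimated correlation), with the junction cadherin Cdh5 at 0.91.

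Lower with LPS than with oxPAPC were 13 of 23 NRF2 targets, 17 adjusted over the list alone (camera adjusted p = 1.08e-12, adjusted p = 0.134 with an estimated correlation), with Gclm at −2.18 ± 0.25 (adjusted p = 0.00063) and Hmox1 at −1.94. Of 12 heat shock genes 7 were lower, 9 adjusted over the list alone (camera adjusted p = 1.48e-06, adjusted p = 0.252 with an estimated correlation), and of 11 sterol genes 3, 5 adjusted over the list alone (camera adjusted p = 0.00158, adjusted p = 0.252 with an estimated correlation), with Idi1 at −1.62. The largest differences downwards were Slc40a1 (−3.71 ± 0.31, adjusted p = 6.08e-05), Cks2 (−2.36) and Lpl (−2.36). Slc40a1 and Cks2 with LPS and Il6 with oxPAPC averaged below the 40th percentile of their arrays. Immediate early genes (5 lower, 1 higher of 18), coagulation genes (2 of 12 higher), antigen presentation (1 of 11 higher), lipid genes of the PPAR list (3 of 18 lower), matrix genes of the TGF-beta list (1 of 19 lower) and smooth muscle markers (0 of 16 called) also passed camera (adjusted p = 0.00094, 0.002, 0.0152, 0.032, 0.036 and 0.036). None did with an estimated correlation (adjusted p = 0.252, 0.252, 0.492, 0.252, 0.454 and 0.657), and with the smooth muscle covariate antigen presentation (median 0.34 to 0.24, adjusted p = 0.0794) and the TGF-beta list (−0.28 to −0.14, adjusted p = 0.14) were lost too. The count was 320 and 261 without LPS replicates 3 and 4, 259, 244 and 1206 without oxPAPC replicates 11, 12 and 13, 341 with the smooth muscle covariate, and 326 with only the 2 groups.

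**Figure D3:**
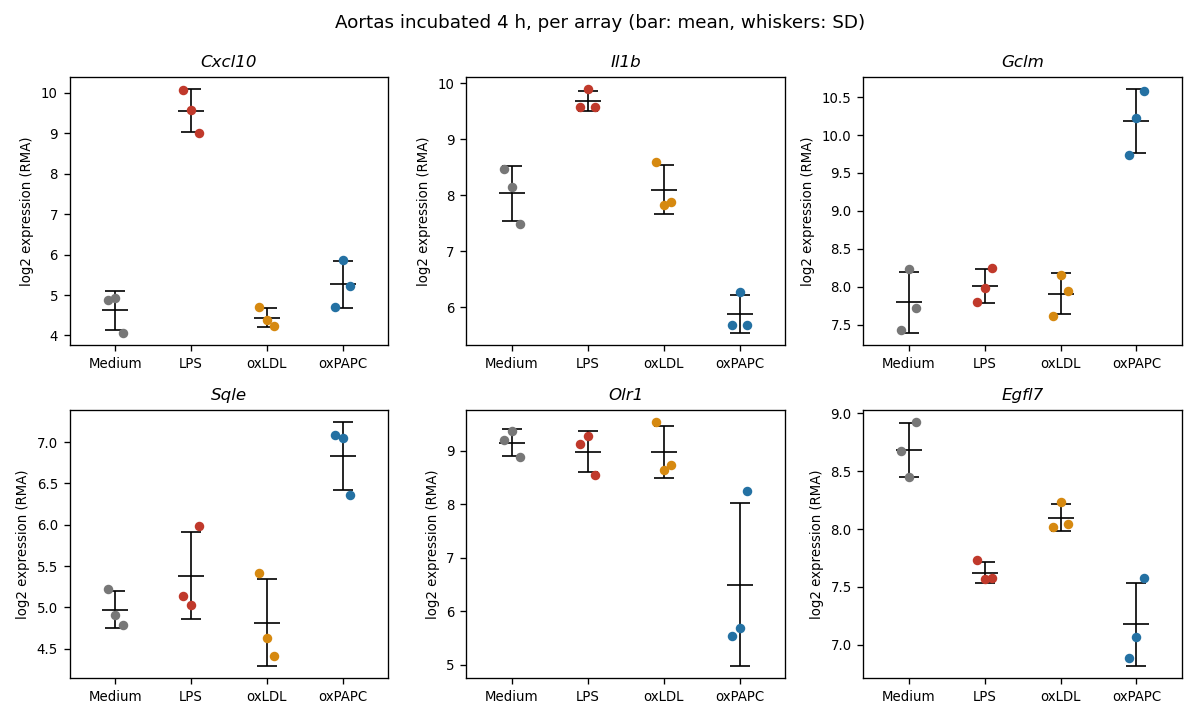
Log2 expression of Cxcl10, Il1b, Gclm, Sqle, Olr1 and Egfl7 on each incubated array (points) in the 4 incubated groups, with means (bars) and SD (whiskers), n = 3 each. Cxcl10 averaged 9.55 with LPS and 4.62 in medium, Gclm 10.2 with oxPAPC and 7.79 in medium, and Olr1 with oxPAPC had an SD of 1.52.

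LPS and oxLDL shared 90 genes called in the same direction (18 higher, 72 lower, none opposite), where independent lists would share 1.88 and 8.86. LPS and oxPAPC shared 353 (110 higher, 243 lower, 12 opposite), where independent lists would share 21.2 and 55.5, and oxLDL and oxPAPC shared 114 (30 higher, 84 lower, 3 opposite), against 4.67 and 20.2. Simulated unchanged groups that shared 3 control arrays had at most 1 such gene in common, but such groups call almost no gene, so this sets no bar. In a test chosen after the data were seen, the residuals of the incubated arrays were dealt into unchanged groups with 1 shared control 100 times, and as many genes as each stimulus called were taken by rank. The pairs then shared 78.9, 301 and 116 genes on average in the same direction, and as many as the real 90, 353 and 114 in 42, 35 and 55 draws, so the number of shared genes alone does not part the stimuli from their shared controls. Fold changes correlated across genes, which are not independent replicates, at 0.547, 0.543 and 0.551 (simulated 0.499, 0.5 and 0.499), with covariances of 0.103, 0.144 and 0.121 beside simulated 0.0266, 0.0265 and 0.0265. The 3 control arrays cannot be split, so part of the excess may come from sharing them. Fabp5 fell with all 3 stimuli, and smooth muscle markers were higher with all 3.

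Medium for 4 h was also set against fresh wild type, a contrast the design does not name. The age of the incubated animals is not given, and their sample titles name no strain or genotype. The lists of ATF4 targets, NF-kB feedback, hypoxia and cytokines lay higher and smooth muscle markers lower. With an estimated correlation the first 2 kept their calls (adjusted p = 0.0127 and 0.034), and hypoxia (adjusted p = 0.268), cytokines (adjusted p = 0.112) and smooth muscle (adjusted p = 0.57) lost them. Ptgs2, cyclooxygenase of prostaglandin synthesis, rose 77.2-fold (log2 6.27 ± 0.34, adjusted p = 3.75e-07, n = 3 and 6) and Olr1 by 5.82 ± 0.13. Olr1 averaged below the 40th percentile of the fresh arrays and lay 22.5-fold above that level after incubation. Nrep had the largest fall (−5.02 ± 0.14, adjusted p = 4.55e-09).

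Of 20 ATF4 targets, genes of amino acid deprivation, 19 rose, also adjusted over the list alone (camera adjusted p = 3.24e-12, adjusted p = 0.0127 with an estimated correlation), with Chac1 at 5.80 ± 0.14, the amino acid transporter Slc7a5 at 5.38 and asparagine synthetase Asns at 5.14 ± 0.15. Hypoxia and glycolysis genes rose for 15 of 20 and fell for 1, also adjusted over the list alone (camera adjusted p = 1.16e-06, adjusted p = 0.268 with an estimated correlation), among them Egln3 (4.14), Adm (3.62) and the glucose transporter Slc2a1 (3.08). NF-kB feedback genes rose for 10 of 12, also adjusted over the list alone (camera adjusted p = 1.45e-06, adjusted p = 0.034 with an estimated correlation), with Ier3 at 3.27 and Bcl3 at 2.97. Cytokines rose for 8 of 10 and fell for 1, also adjusted over the list alone (camera adjusted p = 0.000405, adjusted p = 0.112 with an estimated correlation), with Cxcl2 at 4.12 ± 0.22, Lif at 4.22 and Il1b at 3.74 ± 0.20. Immediate early genes rose for 14 of 18 and fell for 1, also adjusted over the list alone (camera adjusted p = 6.73e-06, adjusted p = 0.198 with an estimated correlation), with Fosb at 4.90, Myc at 4.09 and Egr2 at 3.88. Coagulation genes rose for 9 of 12 and fell for 1, 10 and 2 adjusted over the list alone (camera adjusted p = 0.000295, adjusted p = 0.034 with an estimated correlation), with Plau at 4.42 and tissue factor F3 at 3.48.

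Macrophage markers rose for 11 of 13 and fell for 1, also adjusted over the list alone (camera adjusted p = 0.000366, adjusted p = 0.268 with an estimated correlation), with Cd68 at 2.29 and Ctss at 1.86, while Cd163 fell by 1.79. Heat shock genes rose for 8 of 12, also adjusted over the list alone (camera adjusted p = 0.003, adjusted p = 0.324 with an estimated correlation), with Bag3 at 2.26. NRF2 targets rose for 9 of 22 and fell for 4, also adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.268 with an estimated correlation), with Hmox1 at 5.34 ± 0.25, Srxn1 at 2.32 and Txnrd1 at 2.24. Leukocyte adhesion genes rose for 6 of 12 and fell for 3, 7 and 3 adjusted over the list alone (camera adjusted p = 0.0449, adjusted p = 0.198 with an estimated correlation), with Sele at 2.98, Cd44 at 2.95 and Selp at 2.31, a call lost with cyclic loess without a smaller median (0.52 to 0.59, adjusted p = 0.069). Oxidative phosphorylation genes fell for 14 of 29, also adjusted over the list alone (camera adjusted p = 0.0197, adjusted p = 0.324 with an estimated correlation), with Ndufb3 at −1.27. Smooth muscle markers fell for 13 of 16, also adjusted over the list alone (median −0.96, camera adjusted p = 0.00612, adjusted p = 0.57 with an estimated correlation), with Cnn1 at −1.82 and Acta2 at −1.28. Fibroblast markers fell for 8 of 11 and rose for 2 (camera adjusted p = 0.0748), and passed, lower, with either scaling (adjusted p = 0.0359 and 0.049). Their collagens Col1a1 and Col3a1 fell by 3.07 and 2.61, and elastin, Eln, fell by 2.13. The TGF-beta matrix list, which holds Eln, had 5 higher and 9 lower of 18, also adjusted over the list alone, and did not pass (camera adjusted p = 0.526).

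In all 4410 of 7508 genes changed (58.7%), 1824 higher and 2586 lower, and the median of all genes was −0.13. Cyclic loess gave 2158 higher and 2084 lower at a median of −0.01, and median centring 1956 and 2366, so the excess of falls depends on the scaling. The count was 2175 with the smooth muscle markers as a covariate, under which Postn turned from a fall to 0.04. Every list call but that of the smooth muscle markers was kept under the covariate. Medians were smaller for NRF2 targets (0.24 to 0.15), leukocyte adhesion (0.52 to 0.34), cytokines (1.71 to 1.16), macrophage markers (1.31 to 1.13) and NF-kB feedback (1.70 to 1.54). Interferon-response (camera adjusted p = 0.0403), fibroblast (0.0403) and erythroid and platelet genes (0.0185) then passed as lower. Scavenger receptors (0.0481) and p53 targets (0.0403, though with a median of −0.02) passed as higher. In fresh wild type Adm, Asns, Bcl3, Cd68, Chac1, Egln3, F3, Hmox1, Il1b, Lif and Slc7a5 averaged below the 40th percentile of their arrays, as did Cd163 in medium, and after incubation Asns, Chac1 and Il1b lay 4.56, 4.27 and 3.37 above that level. Of 88 named genes 86 passed under every array left out.

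The ex vivo responses were then looked up in the knockout. Of each set of 100 genes, 74 to 97 were tested there, and all 6 sets lay in their own direction: genes raised by LPS, oxLDL and oxPAPC had medians of 0.09, 0.07 and 0.14 in the knockout against wild type (camera adjusted p = 0.0101, 0.0014 and 2.43e-05). Genes lowered by them had medians of −0.19, −0.14 and −0.15 (camera adjusted p = 3.27e-06, 0.00121 and 0.000369). With an estimated correlation none passed (adjusted p = 0.116 to 0.354), and with 50 genes per set the genes raised by LPS did not (17 of 31 higher, adjusted p = 0.434). Smooth muscle markers were higher in the knockout and with each stimulus, and with these markers as a covariate in the knockout comparison, a fit chosen after the data were seen, 1 of the 6 sets passed, the genes lowered by LPS (adjusted p = 0.028; the others 0.205 to 0.622). The medians were then 0.10, 0.04 and 0.03 for genes raised by LPS, oxLDL and oxPAPC and −0.12, −0.08 and −0.06 for genes lowered. The sets are not independent, since the 3 stimuli share their medium arrays and 10 to 32 genes of any pair of sets in the same direction were the same. For 100 draws of unchanged groups, made from the residuals of the incubated arrays with 1 shared control group and also chosen afterwards, at least 1 set passed in 65 draws. All 6 sets lay in their own direction in 7 and all against it in 12, and all passed in 1 and 3 of them.

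**Figure D4:**
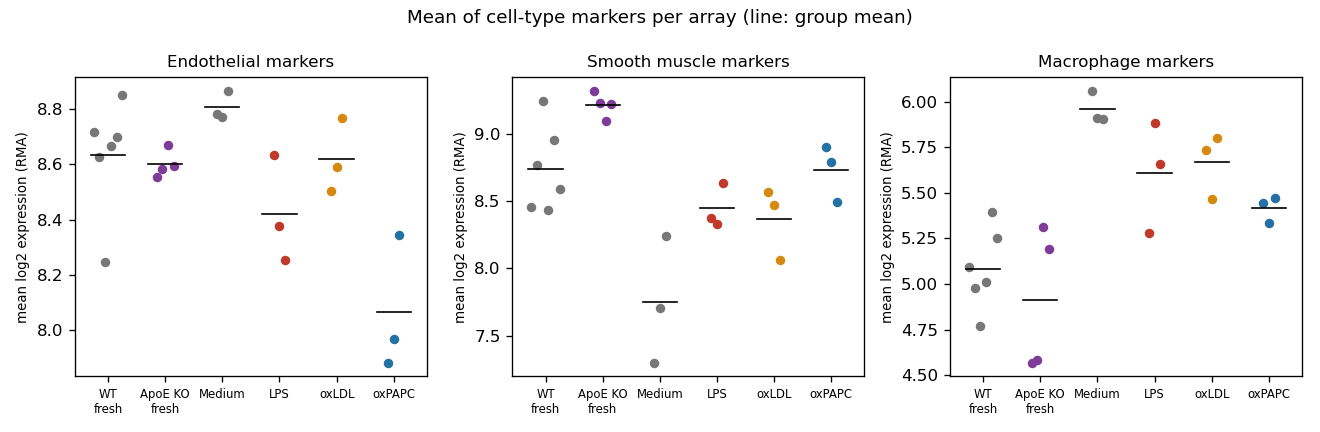
Mean log2 level of endothelial, smooth muscle and macrophage markers on each array (points) in the 6 groups, with group means (lines). Smooth muscle markers averaged 7.75 in medium, 8.45 with LPS, 8.36 with oxLDL, 8.73 with oxPAPC, 8.74 in fresh wild type and 9.22 in the fresh knockout.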

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

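Of the tests in this part, the check of Nectin2's second probe set and the counts over other splits of the arrays were set before their results were seen, and the others were chosen afterwards. The reading of the Nectin2 check was changed after its result was seen.

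In 185 tests for a value far from the others of its group, 9 values stood out, where chance marks about 1 in 20 groups (9.25 here). Critical values were set only for groups of 4 and 6 arrays, the sizes of the fresh groups. Nothing about the incubated groups of 3 can be read from these tests. Each of the 9 values is given with its gap as a share of the group's range. In the knockout group these were Cuedc1 in replicate 6 (0.937; 6.49, nearest array 6.72), H2-M3 in replicate 3 (0.832; 6.71, nearest 7.43) and Serpina1b in replicate 6 (0.927; 3.37, nearest 3.78). In wild-type replicate 12 they were Ppbp (0.72; 4.08, nearest 6.39), Col3a1 (0.686; 11.78, nearest 11.56) and the mean of the endothelial markers (0.628; 8.25, nearest 8.63). In wild-type replicate 14 they were Thbd (0.706; 10.02, nearest 10.27), Tnnc2 (0.657; 5.39, nearest 4.82) and Sesn2 (0.651; 4.22, nearest 4.13).

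Nectin2 lies close to Apoe, and its rise was the largest among the genes called in the knockout. A sequence variant under a single probe set may still explain it. The bound set beforehand against this, every other probe set higher by over 2 SE, was met by 1 other probe set, the only other for Nectin2 (0.56 ± 0.0946, adjusted p = 0.053 over every probe set). That bound left out the level, and at 3.72 and 4.28 the probe set lay below the 40th percentile of its arrays, so it was too weak to exclude a variant. A flanking segment of another strain, carried along with the targeted allele, could raise or lower several neighbours, but 1 of 101 tested genes within 10 Mb of Apoe was called (Fisher's exact p = 0.353), which decides neither way. An effect of the targeted allele on its neighbour and a response to hyperlipidemia stay open, and neither was tested.

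With oxPAPC, smooth muscle markers were higher and endothelial markers lower than in medium. The changes of the 17 endothelial markers differed by far more than their errors (Q over its degrees of freedom 8.92, range −1.56 to 0.38). A lower share of endothelial cells would shift them alike only if every signal scaled alike and no other cell expressed them. That premise was not checked, so a lower share as the whole cause stays open. Smooth muscle carried over in varying amounts is a candidate source. Residuals of the 16 markers correlated within the incubated groups (mean r = 0.598, against a median of −0.0041 and a 95th percentile of 0.067 for 1000 random lists). The random lists were matched by level alone. Joint regulation of these markers would give such a correlation too, so it cannot tell this from carry-over. All 5 of the most abundant markers were higher, Myh11 for example at 11.5 with oxPAPC and 10.4 in medium. All 16 passed the level filter in fresh and in incubated arrays, no other list holds any of them, and the protocol of scraping names no step that would remove such cells. A direct rise of these genes with oxPAPC stays open as well. Their changes from 0.0992 to 1.93 also differed by more than their errors (Q over its degrees of freedom 3.67), which decides neither way.

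Cytokine and NF-kB genes rose in medium alone. Endotoxin in the medium was looked at through the interferon genes that LPS raised over oxLDL. Of these, 8 of 10 passed the level filter in this comparison. Their median change was −1.01 in medium against fresh wild type, 7 of them lower (exact sign-flip p = 0.0156). That p takes genes on the same arrays as independent. No incubated group known to be free of endotoxin was measured. A fall of these genes in culture could therefore hide a rise, and endotoxin stays open. The 6 most abundant macrophage markers, all higher, rose by unequal amounts (0.20 for Fcer1g to 1.86 for Ctss, Q over its degrees of freedom 5.67). Of the 18 macrophage markers 1 is also in another list. Unequal rises cannot exclude more macrophages as the whole cause, since signals need not scale alike with the number of cells. A response to isolation and culture, and a difference in age, stay open as untested.

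Other splits of the same arrays were counted for each comparison. In the fresh arrays 2 of 100 splits, the real one included, called as many genes as the real 31, a share under the 0.05 set beforehand for excluding chance. The highest other called 96, with wild-type replicates 7, 8, 13 and 15 set apart, which points to a structure among the arrays besides genotype. That split follows the smooth muscle markers (means of 8.43 to 8.77 in these 4, 8.95 to 9.32 in the other 6), which were also higher in the knockout, so the count of 31 does not part genotype from them. For medium against fresh wild type, chance could be excluded: 1 of 84 splits, the real one, called 4410 genes and the highest other 1. For groups of 3 the 10 splits are too few for a share under 0.05: the real split alone (1 of 10) called 683 genes with LPS (highest other 0), 212 with oxLDL (0), 1606 with oxPAPC (0), 383 between LPS and oxLDL (0), 653 between LPS and oxPAPC (8) and 934 between oxLDL and oxPAPC (1).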

How the results depend on the processing

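The number of arrays limits the precision, and transcripts near background, Apoe among them, could not be followed above the level filter. In the comparisons with counts of called genes, no paired analysis was possible because no 2 groups compared share as many as 2 replicate numbers. OxLDL against fresh wild type, used only to choose gene sets, is not among these comparisons, and pairing was not tested there. For the called genes named in the text and the 9 others named with values, 6830 results across the alternatives kept direction and side of the threshold, 1443 lost the threshold, 19 gained it and 4 turned. For gene lists 535 kept their call and 124 lost it, 62 of these with an estimated correlation. That tally covers the estimated correlation, fry, the mean of a gene's probe sets and each array left out. It leaves out the other scalings and the smooth muscle covariate, whose effects on lists stand beside each comparison. By number, most losses for genes came from leaving out an array (824 lost, 2233 kept), where fewer arrays entered the fit. For lists 41 were lost and 417 kept that way. The smooth muscle covariate entered far fewer results but lost more of them (234) than it kept (211). It raised most standard errors and made many changes smaller. The median absolute change of called genes went from 0.817 to 0.655 with oxPAPC and from 0.841 to 0.712 in the knockout. With LPS it hardly moved (0.823 to 0.819). The covariate turned Col3a1 (−0.169, adjusted p = 0.864), Myl9 (−0.0523, adjusted p = 0.934) and Rbp4 (−0.0576, adjusted p = 0.965) with oxPAPC, and Postn (0.0385, adjusted p = 0.926) in medium. Myl9 is itself part of that covariate. Under both other scalings 11 of 20 named genes kept their call in the knockout, 47 of 59 with LPS, 24 of 27 with oxLDL, 79 of 87 with oxPAPC and 87 of 88 in medium.

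For the knockout, 31 genes became 6 with no filter, 15 with median centring, 72 with array weights, 94 with all 22 arrays in 1 fit, 7 at 2-fold and 1 with the smooth muscle covariate. For LPS, 683 became 1406 with array weights, 1098 with all 22 arrays, 211 at 2-fold and 118 with the covariate. For oxLDL, 212 became 428 with every probe set on its own, 518 with array weights, 554 with all 22 arrays, 90 at 2-fold, 16 with the covariate and 64 with only the 2 groups. For oxPAPC, 1606 became 2917 with array weights, 510 at 2-fold and 0 with the covariate (limma, 1089 at an unadjusted p under 0.05). For medium against fresh wild type, 4410 became 1764 at 2-fold and 2175 with the covariate. LPS against oxLDL moved from 383 to 662 with all 22 arrays, 121 at 2-fold and 210 with only the 2 groups. LPS against oxPAPC moved from 653 to 2040 with array weights, 279 at 2-fold, 341 with the covariate and 326 with only the 2 groups. OxLDL against oxPAPC moved from 934 to 1767 with array weights, 269 at 2-fold, 379 with the covariate and 543 with only the 2 groups. At 2-fold the shared calls fell to 27 for LPS and oxLDL, 76 for LPS and oxPAPC and 36 for oxLDL and oxPAPC. The 2-fold counts are lower by construction; for the rest the cause was not tested.

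With an estimated correlation the called lists went from 5 to 0 in the knockout, 7 to 0 with LPS, 3 to 0 with oxLDL, 15 to 0 with oxPAPC, 12 to 3 in medium, 3 to 0 for LPS against oxLDL, 14 to 2 for LPS against oxPAPC, 8 to 0 for oxLDL against oxPAPC, and 6 to 0 for the ex vivo sets in the knockout, where the smooth muscle covariate, an alternative chosen after the data were seen, left 1. Fry gave 0 in the knockout, 0 with oxLDL, 20 in medium and 6 for LPS against oxLDL, and the mean of a gene's probe sets gave 1 list with oxLDL.

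Leaving out 1 array at a time gave 1 to 68 genes and 3 to 6 lists in the knockout, 236 to 374 and 6 to 8 with LPS, 23 to 269 and 1 to 6 with oxLDL, 735 to 1999 and 11 to 17 with oxPAPC, and 3724 to 4381 and 11 to 13 in medium. It gave 133 to 266 and 3 to 7 for LPS against oxLDL, 244 to 1206 and 11 to 14 for LPS against oxPAPC, and 348 to 1370 and 7 to 14 for oxLDL against oxPAPC. The arrays that moved a count of genes by more than 1.5 times stand beside each comparison. The number of called lists moved as far for the knockout (5 to 3 without wild-type replicate 14), for oxLDL (3 to 1 without medium replicate 9 or oxLDL replicate 15, to 6 without medium replicate 10), for LPS against oxLDL (3 to 5 and 7 without LPS replicates 3 and 10) and for oxLDL against oxPAPC (8 to 14 without oxPAPC replicate 13). With 2 arrays left in a group, the fit took their spread to be like that of the other groups.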

Other observations

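In medium against fresh wild type, where 58.7% of all genes were called, several lists that did not pass camera also held called genes. Of 17 p53 targets 8 rose and 5 fell against fresh wild type (camera adjusted p = 0.14), with the growth arrest genes Gadd45a at 4.22 ± 0.35 (adjusted p = 4.25e-06, n = 3 and 6), Sesn2 at 3.59 ± 0.17 and Cdkn1a at 3.42 ± 0.17. Of 11 cell cycle genes 6 fell and 2 rose (camera adjusted p = 0.164), among them Mki67 (−2.19 ± 0.29) and Ccna2 (−1.53). Of 11 antigen-presentation genes 4 rose and 1 fell (camera adjusted p = 0.375), with the class II genes H2-Ab1 (1.92) and Cd74 (1.83) higher, next to macrophage markers that rose for 11 of 13. Erythroid and platelet genes fell for 5 of 8 (camera adjusted p = 0.164), with the anion exchanger Slc4a1 at −2.06, Alas2 at −1.66 and Hba-a1 at −1.57. Sesn2 in fresh wild type and Slc4a1 in medium averaged below the 40th percentile of their arrays. Counts adjusted over the list alone were the same for these 4 lists.

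In medium the fatty acid oxidation genes Acadm (−1.52 ± 0.21) and Cpt1a (adjusted p = 1.95e-05) fell, and the transporter Cd36 rose (2.07 ± 0.54). Of 16 genes of the PPAR list 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.375). Sterol synthesis genes rose for 5 of 11 and fell for 2, also adjusted over the list alone (camera adjusted p = 0.164), with Msmo1 at 1.95 and Dhcr7 at −0.96, each below the 40th percentile of its arrays in its lower group. Abcg1 rose in medium (2.83-fold, adjusted p = 0.000452) and in the knockout (1.32 ± 0.21), and fell with LPS (−1.04 ± 0.26) and oxPAPC (−1.32 ± 0.26). Lpl fell with LPS and rose with oxPAPC, a difference of −2.36 ± 0.29 (adjusted p = 0.000759, n = 3 and 3).

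Both tests of the following hypothesis were chosen after the results were seen, and the bound against it was redrawn later still, to ask for a called shift upwards. OxPAPC may counter part of the response to incubation, since Olr1, Il1b and Bcl3 rose in medium and fell with oxPAPC. The 100 genes with the highest t in oxLDL against fresh wild type, a contrast that leaves out the medium arrays, had a median of −0.33 with oxPAPC against medium, with 69 of 100 lower, 29 called lower and 9 called higher (camera adjusted p = 0.00374, adjusted p = 0.562 with an estimated correlation). The 95 tested genes with the lowest t in that contrast, which a countering effect would raise, had a median of −0.03 with oxPAPC, with 49 lower (camera adjusted p = 0.896), so the hypothesis reaches at most the raised genes. Smooth muscle markers, which fell in medium and rose with oxPAPC, moved along with it, so a varying share of other cells could give part of this shift. The same genes had a median of −0.07 with LPS (camera adjusted p = 0.988), which decides neither way. The 95 lowered genes fell further with LPS (median −0.28, 78 lower, camera adjusted p = 3.05e-05, adjusted p = 0.305 with an estimated correlation), the opposite of countering. Whether the sets' shifts differed between oxPAPC and LPS was not tested.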
